A study of Mus musculus with 4 samples.

How the data were processed

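Nuclei of the posterior substantia innominata, a basal forebrain region between striatum and hypothalamus, were profiled by droplet single-nucleus RNA sequencing in wild-type mice aged 8 weeks. Per the labels, 2 libraries came from males and 2 from females, and the stated aim was to quantify sex differences in the neurons of this region. The labels do not say whether the libraries of 1 sex came from separate animals, so p-values measure only the spread between these samples, which may be technical. Replicate numbers name the libraries and were not used to pair males with females.

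The authors deposited, for each library, a sparse matrix of whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, with lists of gene identifiers, gene symbols and barcodes. Per the submitters' processing notes, Cell Ranger 6.0.1 and Seurat 5 were used with the mouse build mm10. Per the file headers, the matrices were written by Cell Ranger 9.0.1 for both males, 7.0.0 for female 1 and 7.2.0 for female 2. The gene lists of male 1 and male 2 were identical, and those of female 1 and female 2 differed from them and from each other. The labels' protocols name Chromium 3′ reagents of both version 2 and version 3, and the kit of each library is not given in the sources used here. No barcode was shared between a male and a female library, whereas 23 were shared by the males and 35 by the females. Of the barcodes of male 1, 90.8% began with 7 bases also seen at the start of a male 2 barcode and 7.2% with a start seen in female 1. Barcode set, software version, gene list and sequencing depth therefore changed together with sex, and no fit can hold them apart from it. The barcode sets point to a change of chemistry as well, which the labels do not state.

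Counts were analysed over the 31899 genes listed in all 4 libraries by identifier, which held 99.5% of the UMIs of each male library, 97.7% of female 1 and 99.6% of female 2. Of these genes, 31851 were found in GENCODE vM21 (GRCm38), from which coordinates were taken, including 1070 on chromosome X and 704 on Y. The deposited counts summed to 158132452 UMIs in male 1, 144035342 in male 2, 53098268 in female 1 and 53679351 in female 2. Median UMIs per barcode were 10801, 10400, 4180 and 3697 in the same order, over 9480, 9157, 10965 and 10930 barcodes.

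Nuclei were kept with at least 500 and at most 8000 genes and under 5% of counts from mitochondrially encoded genes. Doublets were scored with the Scrublet method in scanpy, library by library. Its automatic threshold marked 0.01% of each male library, 8.51% of female 1 and 10.1% of female 2, so it had not worked in the males. As fixed in advance, the highest-scoring barcodes were removed at 0.8% per 1000 barcodes, which took out 7.6% of male 1, 7.3% of male 2, 8.8% of female 1 and 8.7% of female 2. The upper limit on genes removed 545 and 506 barcodes of the males and 14 and 10 of the females. There remained 8205 nuclei of male 1, 7973 of male 2, 9922 of female 1 and 9642 of female 2, with median UMIs of 10054, 9671, 3947 and 3594.

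Counts were scaled to 10000 per nucleus and log-transformed, 2000 variable genes were chosen with library as batch and without sex-linked and mitochondrial genes, and nuclei were clustered by the Leiden method (30 components, 15 neighbors, resolution 1). Each cluster was named from markers fixed in advance, and every name ends in "-like". The mean marker level of a cluster was divided by that of the highest cluster. Values above 0.6 were required for neurons, 0.25 for oligodendrocytes, astrocytes and microglia, 0.5 for oligodendrocyte precursors (OPCs) and vascular cells, 0.6 for newly formed oligodendrocytes and 0.35 for cholinergic neurons, and these thresholds were set after the clusters had been seen. Clusters with markers of neurons and of a glial or vascular class other than OPCs were called mixed and left out of the class comparisons, as was Leiden cluster 28, which had markers of astrocytes and oligodendrocytes without those of neurons. A neuron cluster with more markers of another class than of its own among its 10 leading genes was left as other neurons. The neuron clusters, but not the other clusters, were also checked for at least 3 markers detected. Detection meant at least 1.5% of nuclei and at least 2 times the share in a class that should lack the marker.

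UMI counts were summed per library and class, since nuclei are not replicates. Classes with at least 30 nuclei in every library were compared between males and females with the edgeR quasi-likelihood test (TMM scaling, filterByExpr), two-sided, with Benjamini-Hochberg adjustment at 0.05, and folds are male over female. CPM values are these sums divided by the library's TMM-scaled total and multiplied by 1e6. Shares of nuclei were tested with edgeR's quasi-likelihood test on numbers of nuclei, and single-library shares have exact Clopper-Pearson 95% intervals that cover counting error only. The share of GABAergic-like among GABAergic-like and glutamatergic-like neurons, a single value, was tested with edgeR's quasi-likelihood test, as planned. It was also tested by an exact permutation over all 6 regroupings of the libraries, two-sided, which for 2 against 2 cannot go below p = 0.333. Neurons were clustered again after anchor-based integration across libraries (Seurat, reciprocal PCA, 2000 variable genes without sex-linked genes, 30 components, resolution 1). These neuron clusters carry numbers of their own, distinct from those of the Leiden clusters of all nuclei. Whether the sex effect differed between GABAergic-like and glutamatergic-like neurons was tested as an interaction with library as a term.

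Also tested with limma's camera (preset correlation 0.01) were 20 gene lists: Y-linked genes, X-linked escape genes, steroid receptors and steroidogenic enzymes, neuropeptides, neuropeptide and hormone receptors, monoamine, acetylcholine, adenosine and cannabinoid receptors, GABA and glycine receptors, glutamate receptors, voltage-gated channels, synaptic adhesion molecules, synaptic vesicle and release machinery, immediate early genes, heat shock genes, clock genes, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, oligodendrocyte and astrocyte transcripts, and striatal projection neuron markers. Designs, lists, markers, filters and the first group of alternative settings given below were set before the data were examined. The rule for named genes took, among called genes with a mean log2 CPM of at least 4, both males on 1 side of both females and a symbol that is not a gene-model name, the 10 largest folds per direction in neurons, GABAergic-like and glutamatergic-like neurons and the 3 largest in other classes. It also took up to 4 called members of each list and, called or not, Xist, Ddx3y, Uty, Kdm5d, Eif2s3y, Kdm6a, Esr1, Esr2, Pgr, Cyp19a1 and 1 gene not reported here. Other genes named below were chosen after their values were seen. Reads of overlapping or antisense genes cannot be told apart here, since the strand setting is not given in the sources used here.

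The tests were checked on simulated counts, drawn with the same spread for both sexes. In the real neuron sums the SD of log2 ratios between libraries was 0.105 in the males and 0.735 in the females. The rates below therefore need not hold for the real counts. With the fitted spread in neurons, edgeR called 2% of genes changed by 1 log2 unit and 56% of those changed by 2 units, with 6 unchanged genes called among 19163 simulated, and DESeq2 called 23% and 97% with 75 unchanged genes called. For the interaction, over 17858 genes, edgeR called 82% and 96% for those sizes, with 7 unchanged genes called. For shares of neuron clusters, 57.8% and 98% of changed clusters were called over 100 draws, with 28 unchanged clusters called.

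Alternatives were DESeq2, median-ratio size factors, no low-count filter, genes matched by symbol, doublets kept, at least 1000 genes per nucleus, a mitochondrial share under 1%, other resolutions, no integration, counts thinned to the shallowest library, the replicate number as a block, camera with an estimated correlation, fry, and each library left out in turn. Chosen after seeing the data were: no upper limit on genes, the male libraries summed as 1, no genes overlapped by gene models found in the list of female 1 alone, no neuron clusters mostly from 1 library, no mixed clusters, mixed clusters counted with the neurons (all of them, or those with neuron markers), Leiden cluster 14 alone for the glutamatergic-like neurons, and neurons thinned before clustering. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Seurat 5.3.0.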

Results

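To assess sex differences in the posterior substantia innominata, nuclei from 2 male and 2 female libraries were compared. Neurons made up 65.5% of the nuclei kept in male 1, 65.3% in male 2, 64% in female 1 and 63.2% in female 2, and most were GABAergic-like. Male neurons held a median of 11654 UMIs in male 1 and 11352 in male 2, against 5083 in female 1 and 4886 in female 2. The summed neurons held 72552039, 68906150, 33933017 and 37153835 UMIs in the same order. The male libraries were far closer to each other than the female libraries were. The SD over genes of the log2 ratio between libraries was 0.105 for the males and 0.735 for the females in neurons. The chi-square per degree of freedom was 2.77 between the males and 156 between the females, against 1.49 and 1.82 for random splits of male 1 and male 2. This sets the males apart only from counting noise and does not show that they came from separate animals, and they were kept as 2 libraries because the labels give them as 2.

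To determine which cell types the sexes contained, the nuclei were assigned to classes by fixed markers. GABAergic-like neurons, which carry the GABA synthesis genes Gad1 and Gad2, made up 50.4% of nuclei in male 1 (95% interval 49.3 to 51.5), 49.8% in male 2 (48.7 to 50.9), 46.2% in female 1 (45.3 to 47.2) and 50.5% in female 2 (49.5 to 51.5). Glutamatergic-like neurons made up 9.86%, 10.1%, 10.3% and 8.13%, and cholinergic-like neurons, the acetylcholine-releasing cells of the basal forebrain, 0.85%, 0.94%, 1.09% and 0.88% in the same order. In Leiden cluster 2, a GABAergic-like cluster with a median of 12186 UMIs, 86.3% of nuclei held a Gad2 UMI, against 17.9% in a class that should lack it. In the leading GABAergic-like clusters of female 1 and female 2, 3 and 13, with medians of 5988 and 4003 UMIs, 68.5% and 48.4% held one, and Slc32a1, the vesicular GABA transporter gene, lay at 9.9% in cluster 3 against 10.5% in the class that should lack it. The GABAergic-like share of the GABAergic-like and glutamatergic-like neurons was 83.7%, 83.1%, 81.8% and 86.1%, a male minus female difference of -0.62 percentage points (log2 fold -0.01 ± 0.05 SE). A two-sided exact permutation test of the libraries gave p = 1, and with 2 against 2 such a test cannot reach 0.05. The difference was 1.53 points without female 2, so its direction rests on that library.

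Among glia, astrocyte-like nuclei were 1.62-fold more frequent in the females, with 7.47% in male 1, 7.66% in male 2, 11.8% in female 1 and 12.8% in female 2 (log2 fold -0.70 ± 0.18 SE, adjusted p = 0.0763 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), which did not pass the correction. Oligodendrocyte-like nuclei made up 11.7%, 11.9%, 15.3% and 13.8%, OPC-like nuclei 2.27%, 2.52%, 1.73% and 4.06%, and microglia-like nuclei 2%, 1.67%, 1.56% and 3.05%. Newly formed oligodendrocyte-like nuclei made up 0.76%, 0.51%, 1.05% and 0.63%, and vascular-like nuclei 0.55%, 0.64%, 0.78% and 0.52%. Clusters left as other neurons held 4.35%, 4.43%, 6.4% and 3.6%, and mixed clusters 9.75%, 9.8%, 3.78% and 2.01%. Mixed clusters had the largest fold of all, 3.37 times as frequent in the males (log2 fold 1.75 ± 0.35 SE, adjusted p = 0.0605 by edgeR's quasi-likelihood test), which did not pass either. Their nuclei held median UMIs of 17075 in male 1, 16506 in male 2, 5241 in female 1 and 9404 in female 2, above the medians of all nuclei kept. Whether they are doublets missed in the males, where Scrublet's threshold had not worked, was not tested. Of 11 class shares, 0 passed edgeR's quasi-likelihood test after adjustment and 2 had an unadjusted p under 0.05. Median UMIs per nucleus kept, which can set such shares, were 10054 and 9671 in the males and 3947 and 3594 in the females. Leaving out 1 female library raised the count to 7 (without female 1) or 7 (without female 2). Different Leiden clusters held most of 2 classes in different libraries. Astrocyte-like nuclei lay mostly in cluster 17 in both males, 30 in female 1 and 27 in female 2, and oligodendrocyte-like nuclei in 19, 20 and 29. The leading GABAergic-like cluster also differed, 8 in male 1, 2 in male 2, 3 in female 1 and 13 in female 2, and held 21.8%, 22.4%, 29.6% and 34.8% of that class.

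**Figure D1:**
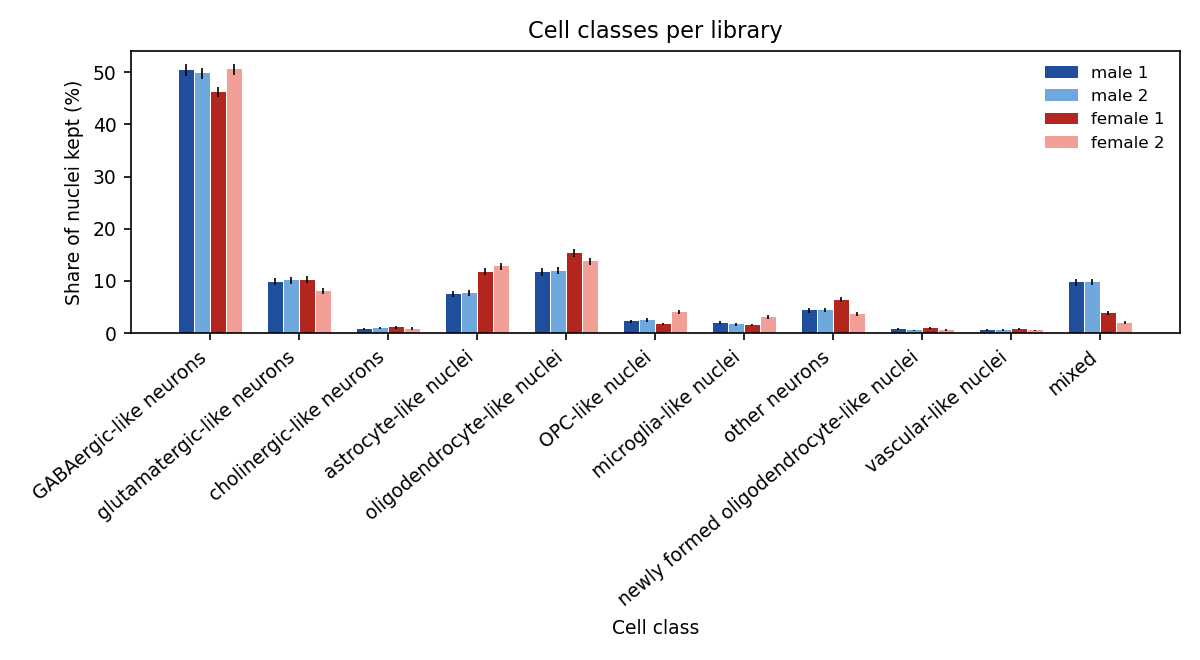
Share of nuclei (%) in each cell class, 1 bar per library (2 males, 2 females), with exact 95% binomial intervals for counting error only. Astrocyte-like nuclei lie at 7.47% and 7.66% in the males and at 11.8% and 12.8% in the females, whereas GABAergic-like shares overlap between the sexes.

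To find genes that differed between the sexes in neurons, UMI counts were summed over all neurons of each library. Xist, the noncoding RNA that silences 1 X chromosome in females, was the gene called. It lay at 1270 CPM in female 1 and 1180 CPM in female 2, against 0.0427 CPM in male 1 and 0.0297 CPM in male 2, from 3 and 2 counts (ENSMUSG00000086503, chromosome X, 103460366 to 103483254; log2 fold -14.96 ± 0.24 SE; adjusted p = 0.00722, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The female level was 35670 times the male level (95% counting interval 15284 to 109859). The Y-linked genes were high in both males and near 0 in both females. Eif2s3y, a translation initiation factor gene, lay at 123 and 128 CPM in the males against 0.0298 and 0 CPM (ratio 8671, counting interval 1556 to 342511; adjusted p = 0.062). Kdm5d, a histone demethylase gene, and Uty, the Y-linked homolog of Kdm6a, had ratios of 951 (407 to 2929) and 612 (387 to 1033), with adjusted p of 0.209 and 0.133. The RNA helicase gene Ddx3y had a ratio of 73 (55 to 100; adjusted p = 0.248). Of the 5 Y-linked genes tested, 0 passed over all genes by edgeR's quasi-likelihood test, 4 passed when adjusted over the list alone, 4 had an unadjusted p under 0.05, and DESeq2 called 4. Usp9y was the fifth, with a log2 fold of -0.25. Xist and the 4 Y-linked genes matched the labelled sex in all 4 libraries.

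Of 19163 genes tested in neurons, 1 was called (0 higher in males, 1 higher in females), and 3285 had an unadjusted p under 0.05. DESeq2 called 1258. The median log2 fold over all genes was -0.056. The count was 3 without male 1 or without male 2, 11995 without female 1 and 12450 without female 2.

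**Figure D2:**
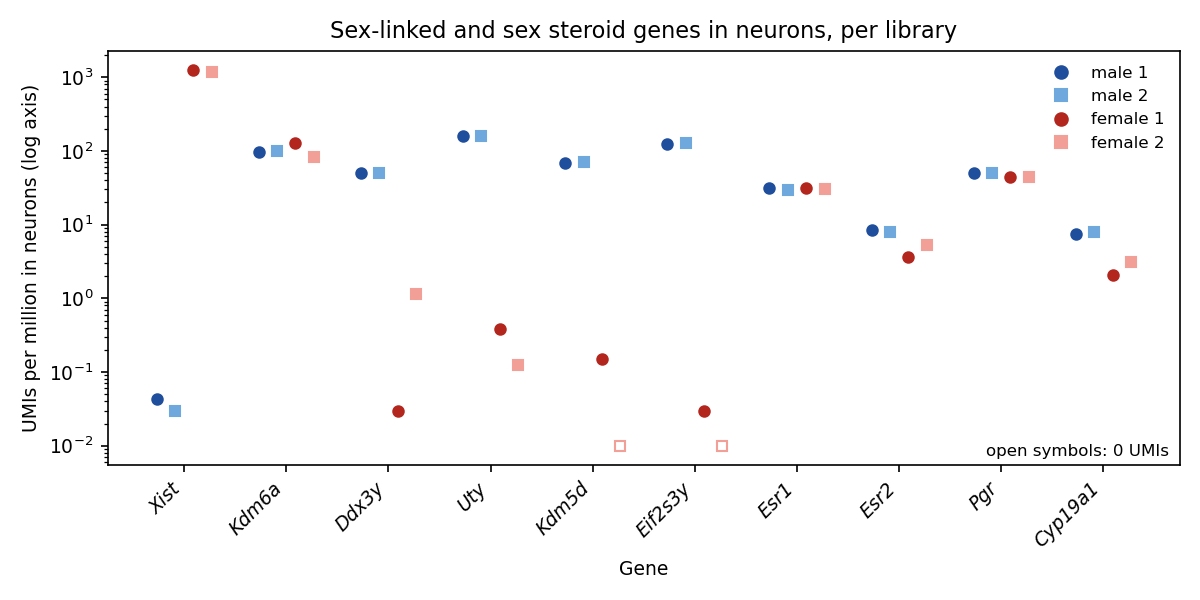
CPM (log scale) of Xist, Kdm6a, 4 Y-linked genes, 3 steroid receptor genes and the aromatase gene Cyp19a1 in the summed neurons, 1 point per library (2 males, 2 females), with open symbols for 0 UMIs. Xist lies at 1270 and 1180 CPM in the females and at 0.0427 and 0.0297 CPM in the males, and the Y-linked genes show the opposite order.

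The steroid receptors and the aromatase gene, through which gonadal hormones act on neurons, were examined next. The estrogen receptor gene Esr1 was nearly equal between the sexes in neurons (log2 fold -0.02 ± 0.12 SE, adjusted p = 0.958). Aromatase, Cyp19a1, which makes estrogen, lay at 7.39 and 7.87 CPM in the males and 2.06 and 3.08 CPM in the females (1.57 ± 0.30, adjusted p = 0.248). The second estrogen receptor gene Esr2 lay at 8.53 and 7.86 against 3.67 and 5.22 CPM (0.88 ± 0.27, adjusted p = 0.262). The progesterone receptor gene Pgr had a log2 fold of 0.19 ± 0.11 (adjusted p = 0.439). The male value lay above the female value in both libraries of each sex for Cyp19a1 and Esr2, and neither passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment. Such separation was common, since 53.1% of all genes tested in neurons had both males on 1 side of both females, against 33.3% by chance. Counts summed over all neurons also move with the shares of neuron clusters. Neuron cluster 40, led by Esr2 and described below, made up 0.97% of male and 0.09% of female neurons. Whether the folds of Esr2, or of Vipr2 given below, came from cluster shares was not tested. Of the 18 genes of this list tested, 0 passed edgeR's test over all genes or when adjusted over the list alone, with 9 log2 folds above 0 and 9 below. At an unadjusted p under 0.05 there were 5, and DESeq2 called 2. Its mean was -0.09, whereas its median and camera's direction were male (adjusted p = 0.325).

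Among X-linked genes that escape inactivation, 1 of 10 was called over all genes and 1 when adjusted over the list alone, Xist in both, and 8 had log2 folds below 0. Eif2s3x had a log2 fold of -0.42, Ddx3x -0.36, Jpx -0.33 and Kdm6a -0.12 ± 0.26 SE (adjusted p = 0.857 for Kdm6a). The list had a median of -0.31 and was not called by camera (adjusted p = 0.0656), whereas limma's fry called it as higher in females (adjusted p = 0.00756).

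To ask whether groups of genes moved together in neurons, the 20 fixed lists were tested with limma's camera. It called 5, of which Y-linked genes (adjusted p = 3.21e-05) and immediate early genes were higher in males, and mitochondrially encoded genes, oligodendrocyte transcripts and astrocyte transcripts were higher in females. With an estimated correlation 0 were called, and camera's count was 14 without female 1 and 4 without female 2. Limma's fry called 4, the Y-linked, oligodendrocyte and astrocyte lists (adjusted p = 0.0391, 0.00756 and 0.0292) and the X-linked escape list, which camera had not called. Immediate early genes, which neurons switch on within minutes of activity, had 14 of 21 log2 folds above 0 and a median of 0.38 (adjusted p = 0.00232 by camera, adjusted p = 0.426 with an estimated correlation). The call was lost without female 2 (adjusted p = 0.163 by camera) and was not made by fry (adjusted p = 0.0917). Fos lay at 10.2 and 9.27 CPM in the males against 4.75 and 4.34 CPM (log2 fold 1.10 ± 0.20), Fosb at 3.15 and 3.38 against 1.46 and 1.21, and Egr4 at 5.97 and 6.15 against 2.21 and 2.32, while Npas4 had a log2 fold of -0.06. Of the 21 genes, 0 passed edgeR's test over all genes or when adjusted over the list alone, 5 had an unadjusted p under 0.05, and DESeq2 called 4.

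In the neurons as defined here, glial transcripts were more abundant in the females. Clusters with markers of both neurons and glia had been left out of the neurons as mixed, which removed 9.48% and 9.73% of male but 3.33% and 1.95% of female nuclei and so acted unequally on this comparison. With these mixed clusters counted with the neurons, an alternative added after seeing the data, camera called 3 lists, and neither the oligodendrocyte list (median -0.56, adjusted p = 0.48) nor the astrocyte list (median -0.77, adjusted p = 0.145) was among them. Without the mixed clusters, all 7 oligodendrocyte genes had log2 folds below 0, with a median of -1.45 (adjusted p = 0.000118 by camera, adjusted p = 0.426 with an estimated correlation). The myelin protein gene Mobp had a log2 fold of -1.77 ± 0.34 and Mbp one of -0.20. Over all genes 0 of the 7 passed edgeR's quasi-likelihood test, 6 passed when adjusted over the list alone, 6 had an unadjusted p under 0.05, and DESeq2 called 5. Of the 8 astrocyte genes, 7 had log2 folds below 0, with a median of -1.02 (adjusted p = 0.0147, adjusted p = 0.457 with an estimated correlation). Apoe lay at 33.6 and 33.1 CPM against 71.4 and 191 CPM, Cst3 at 23 and 21.8 against 43.3 and 137, and Gja1 alone passed when adjusted over the list alone (-1.53 ± 0.25), with 0 over all genes, 5 at an unadjusted p under 0.05 and 3 called by DESeq2. All 13 mitochondrially encoded genes had log2 folds below 0, with a median of -2.07 (adjusted p = 0.0377 by camera, adjusted p = 0.91 with an estimated correlation), a call lost without female 2 (adjusted p = 0.819) and not made by fry (adjusted p = 0.524). Of these, 4 passed edgeR's test when adjusted over the list alone and 0 over all genes, 8 had an unadjusted p under 0.05, and DESeq2 called 7. The respiratory chain genes mt-Nd2 and mt-Cytb lay at 12.9 and 10.1 against 81.7 and 260 CPM and at 46.7 and 51.2 against 145 and 487 CPM. The female libraries disagreed on others, with mt-Co2 at 0.418 CPM in female 1 and 342 CPM in female 2, against 36.6 and 43.9 CPM in the males. Over all barcodes the median mitochondrial share was 0.0114% in male 1, 0.0118% in male 2, 0.0302% in female 1 and 0.2011% in female 2. In all 8 classes compared, glia included, mt-Nd2 was lower in males, with a smallest log2 fold size of 3.28. Its shift is therefore not particular to neurons, and a library-wide difference in mitochondrial RNA was not separated from sex.

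The other 13 lists were not called by camera, and edgeR's quasi-likelihood test called 0 of their 447 genes over all genes or when adjusted over the list alone. Of these genes 42 had an unadjusted p under 0.05, and DESeq2 called 9. GABA and glycine receptors had 15 of 20 log2 folds above 0 (adjusted p = 0.0551), with Gabrg1, a GABA-A receptor subunit gene, at 177 and 184 CPM in the males and 131 and 129 CPM in the females. Monoamine, acetylcholine, adenosine and cannabinoid receptors had 24 of 35 above 0 (0.0656), with the serotonin receptor gene Htr7 at 63.7 and 61.4 against 52.6 and 50.4 CPM. Neuropeptide and hormone receptors split 20 above and 19 below (0.132), with the VIP receptor gene Vipr2 at 8.46 and 9.06 against 3.31 and 3.03 CPM. Neuropeptides had 16 of 24 below 0 (0.604), with Oxt, the oxytocin gene, at 1.21 and 2.57 against 2.06 and 9.96 CPM. Ribosomal proteins had 67 of 79 below 0 (0.128) and oxidative phosphorylation genes 59 of 73 (0.127), and both leanings rest on female 2. Without it both turned to male (adjusted p = 0.000211 and 0.104 by camera), and without female 1 both were called higher in females (adjusted p = 6.31e-14 and 6.79e-08). Clock genes had 11 of 18 above 0 (0.128), with Cry2 at 73.5 and 73.7 against 45.6 and 53.5 CPM, and heat shock genes 11 of 16 below 0 (0.604), with Hsph1 at 31.3 and 33.6 against 49.2 and 48.6 CPM. Synaptic adhesion molecules had 27 of 42 above 0 (0.127), voltage-gated channels 18 of 40 (0.233), glutamate receptors 14 of 24 (0.748), vesicle and release genes 17 of 33 (0.604) and striatal projection neuron markers 3 of 7 (0.779). For channels, glutamate receptors, vesicle genes and striatal markers the median, the mean and camera's direction did not share a sign. Camera's direction was the same for all 20 lists with median-ratio size factors, but 9 turned without female 2: neuropeptides, glutamate receptors, channels, adhesion molecules, heat shock, clock, oxidative phosphorylation, ribosomal and striatal genes. Heat shock genes also turned without male 1.

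**Figure D3:**
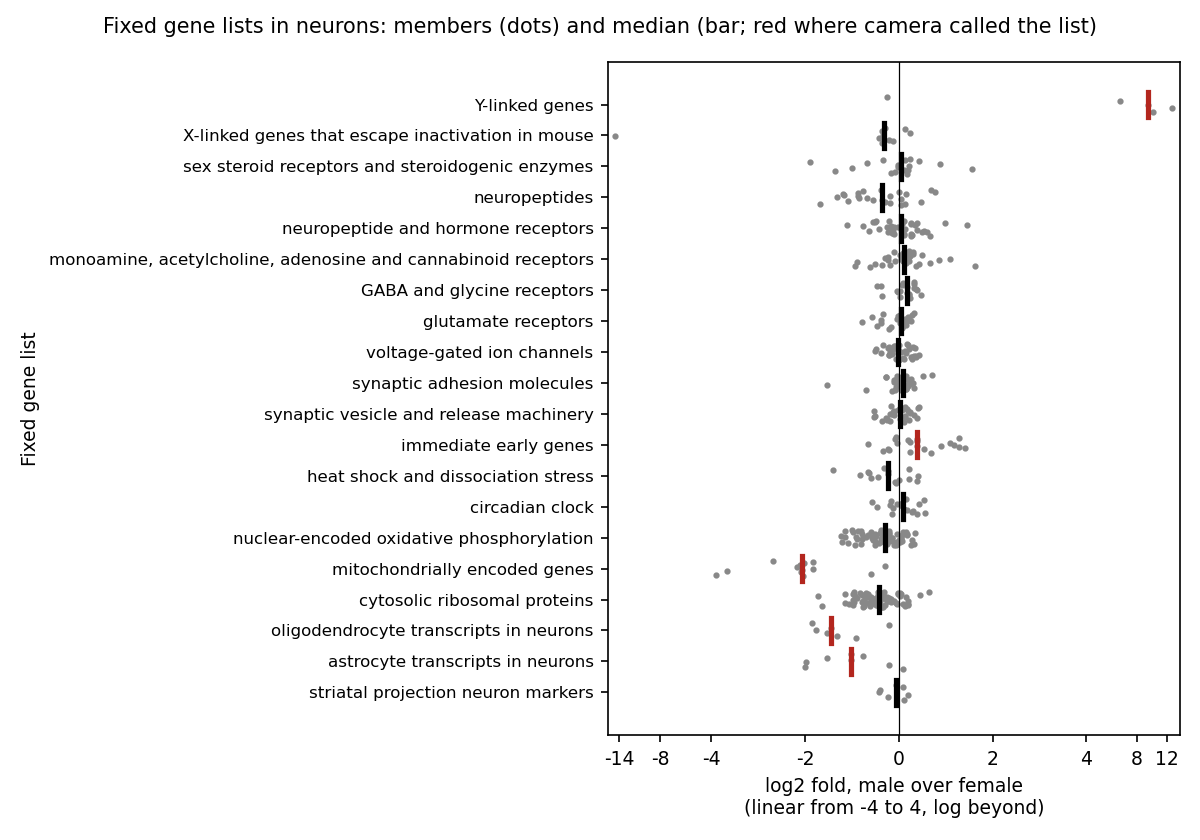
Log2 fold (male over female) of each tested gene of the 20 fixed lists in neurons (axis linear from -4 to 4 and logarithmic beyond). The bar marks the list median, in red where camera called the list. Oligodendrocyte and mitochondrially encoded genes lie below 0 (medians -1.45 and -2.07), and most immediate early genes lie above it (median 0.38).

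To resolve the sex effect by neuron type, the main neuron classes were tested apart. In GABAergic-like neurons Xist was again the 1 gene called of 18486 (log2 fold -14.53, adjusted p = 0.00866 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and the female level was 26432 times the male level (counting interval 11326 to 81408). DESeq2 called 1132, and 3122 genes had an unadjusted p under 0.05. The count was 3 without male 1 or male 2, 11307 without female 1 and 11514 without female 2. Camera called 5 lists in this class, 2 higher in males and 3 higher in females, and 0 with an estimated correlation. Immediate early and mitochondrially encoded genes lost their call without female 2 (adjusted p = 0.392 and 0.645), and astrocyte transcripts without female 1 (0.0655). The count was 8 without male 2 and 14 without female 1.

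In glutamatergic-like neurons 7 genes were called, 6 higher in males and Xist higher in females, by at least 9806-fold against a floor of 3 counts over both males. The Y-linked genes Uty and Eif2s3y were at least 502-fold and 407-fold higher in males against the same floor over the females, and Kdm5d was 638 times higher (counting interval 114 to 25211), all with adjusted p = 0.0233 in edgeR's quasi-likelihood test. The autosomal genes called were Arfip1, which encodes a protein of the Golgi and endosomes, the kinase gene Mapkapk5, and Gm26803, a long noncoding RNA gene. Arfip1 lay at 34.6 and 35.1 CPM in the males and 1.34 and 1.18 CPM in the females (chromosome 3, 84496093 to 84582625; log2 fold 4.77 ± 0.26 SE, adjusted p = 0.0255). Mapkapk5 lay at 38.4 and 39.9 against 0.958 and 0.392 CPM (chromosome 5, 121525038 to 121545905; 5.82 ± 0.38, adjusted p = 0.048), and Gm26803 at 112 and 113 against 9 and 8.82 CPM (chromosome 13, 83723442 to 83729582; 3.66 ± 0.18, adjusted p = 0.0233). All 3 overlap another annotated gene. Their log2 folds were above 2 in all 8 classes compared, glia included, with smallest values of 3.07 for Arfip1, 5.26 for Mapkapk5 and 2.8 for Gm26803. Their shift is therefore not particular to glutamatergic-like neurons. Of 14944 genes tested, 2087 had an unadjusted p under 0.05, and DESeq2 called 593. The 7 genes were called without each library in turn, with counts of 335 (without male 1), 310 (male 2), 6537 (female 1) and 5554 (female 2).

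Camera called 8 of the 20 lists in glutamatergic-like neurons and 0 with an estimated correlation. Immediate early genes had 18 of 20 log2 folds above 0 with a median of 0.66 (adjusted p = 1.3e-05, adjusted p = 0.349 with an estimated correlation). GABA and glycine receptors were also higher in males (adjusted p = 0.0338), and oxidative phosphorylation (0.00645) and ribosomal protein genes (0.00522) were higher in females, with estimated-correlation adjusted p of 0.699, 0.965 and 0.965. Oligodendrocyte transcripts (median -1.76) and astrocyte transcripts (median -1.36) were higher in females here as well, again without the mixed clusters. The calls of GABA and glycine receptors and of oxidative phosphorylation were lost without male 1 (adjusted p = 0.0865 and 0.0813 by camera) or female 2 (0.226 and 0.196), the latter also without male 2 (0.0598). Ribosomal proteins lost theirs without male 1 (0.0516) or male 2 (0.0533) and turned to male without female 2 (0.00693). Mitochondrially encoded genes lost theirs without female 2 (0.82). The count was 5 without male 1, 14 without female 1 and 5 without female 2.

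In cholinergic-like neurons 11 genes were called, 7 higher in males and 4 higher in females. Xist was at least 1658-fold higher in females, and Uty, Eif2s3y, Kdm5d and Ddx3y were at least 105-fold, 68-fold, 39-fold and 32-fold higher in males, each against 3 counts over the other sex. Chpf2, which acts in chondroitin sulfate synthesis, was higher in females at 76 and 78.2 CPM against 17.4 and 18.7 CPM in the males (chromosome 5, 24586741 to 24594556; log2 fold -2.09 ± 0.24 SE, adjusted p = 0.0416, edgeR quasi-likelihood test). Arfip1, Mapkapk5 and Gm26803 were again higher in males, and the gene models Gm11867 (log2 fold -6.41) and Gm26788 (-4.90) were higher in females. Chpf2, Gm11867 and Gm26788 also overlap another annotated gene. Of 9855 genes tested, 985 had an unadjusted p under 0.05, and DESeq2 called 89. The count was 6 without male 1 or male 2, 892 without female 1 and 1422 without female 2. Chpf2, Mapkapk5, Gm11867 and Gm26788 lost their call without male 1 and without male 2 (largest adjusted p 0.438, 0.278, 0.113 and 0.472), Arfip1 without male 2 (0.08) and Gm26803 without male 1 (0.0968).

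The same comparison in glia returned mainly sex-linked genes. In astrocyte-like nuclei 3 genes were called, Xist (ratio 13408, counting interval 2406 to 529604) higher in females and Uty and Eif2s3y at least 270-fold and 235-fold higher in males. In oligodendrocyte-like nuclei the 3 called were Xist (ratio 4349, 1204 to 35918), Uty (679, 121 to 26852) and Eif2s3y (609, 109 to 24083). OPC-like nuclei had 9 called genes, with Xist (ratio 5520, 990 to 218076), its antisense partner Tsix (627, 112 to 24818), mt-Nd2 (log2 fold -4.04) and 8030451O07Rik (-4.43) higher in females, and Uty, Eif2s3y, Kdm5d, Arfip1 (5.12) and 1700110C19Rik (5.79) higher in males. Microglia-like nuclei had 8, with Xist at least 818-fold, Tsix at least 80-fold, mt-Nd2 (-4.69), mt-Cytb (-3.58) and mt-Nd1 (-2.56) higher in females, and Uty, Eif2s3y and Gm26803 (6.75) higher in males. DESeq2 called 79, 95, 79 and 19 genes in the 4 classes. Leaving out 1 library moved the counts to between 29 (without male 2) and 4625 (without female 1) in astrocyte-like, 30 (male 2) and 4538 (female 1) in oligodendrocyte-like, 40 (male 2) and 2091 (female 1) in OPC-like and 25 (male 2) and 510 (female 1) in microglia-like nuclei. Every called gene of these 4 glial classes was called in all 4 of those fits.

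To test whether the sex effect itself differed between GABAergic-like and glutamatergic-like neurons, the interaction of class and sex was fitted with library as a term. It was called for 290 of 17858 genes, with a higher male over female fold in glutamatergic-like neurons for 180 and in GABAergic-like neurons for 110. Sox5, a transcription factor gene of neuronal subtype identity, had log2 folds of 0.90 in GABAergic-like and -0.50 in glutamatergic-like neurons (difference -1.39 ± 0.08 SE, adjusted p = 7.41e-09, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Kctd16, an auxiliary subunit gene of GABA-B receptors, went the other way (-0.07 and 0.78, difference 0.85 ± 0.06, adjusted p = 1.68e-07). Among hormone receptors, the prolactin receptor gene Prlr lay at 59.5 and 62.1 CPM in male against 31.8 and 20 CPM in female glutamatergic-like neurons, and at 94.3 and 89.5 against 76.4 and 71.1 CPM in GABAergic-like neurons (difference 0.91 ± 0.12, adjusted p = 0.000324). In 281 of the 290 genes both males lay on 1 side of both females in the class difference, and in 150 the folds had opposite signs. A call itself favors such separation, so the 281 add no support of their own.

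Members of several lists differed in this way. Synaptic adhesion molecules gave 7 of 42 called and 21 when adjusted over the list alone, among them Ptprd (difference 0.37) and Cntnap4 (-0.50). Glutamate receptors gave 4 of 24 (6 over the list alone), with the AMPA receptor gene Gria3 at 0.55 ± 0.06 (adjusted p = 2.52e-05, edgeR), and neuropeptide and hormone receptors 4 of 39 (10), with the thyroid hormone receptor gene Thrb at 0.48 ± 0.07 (adjusted p = 0.000449). Mitochondrially encoded genes gave 7 of 13 (10), GABA and glycine receptors 2 of 20 (8), with Gabra2 at 0.44, and voltage-gated channels 2 of 40 (6), with Kcnq3 at 0.45. Monoamine and related receptors gave 2 of 33 (6), neuropeptides 2 of 24 (2), vesicle and release genes 2 of 33 (3), immediate early genes 1 of 21 (5), clock genes 1 of 18 (3), steroid receptors and enzymes 1 of 18 (2) and striatal markers 1 of 7 (2), and the other 7 lists gave 0, also over the list alone. DESeq2 called 93. The count was 182 without male 1 and 543 without female 2, and 86 of the 290 genes were called in all 4 fits that left out 1 library. With Leiden cluster 14 alone as the glutamatergic-like neurons, 95 of 288 genes were called again and Thrb had a difference of 0.04. Leiden cluster 15 held 16.9% and 16.2% of the glutamatergic-like neurons of the males against 6.5% and 7% in the females, and cluster 21 held 22.4% and 25.4% against 39% and 44.6%.

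**Figure D4:**
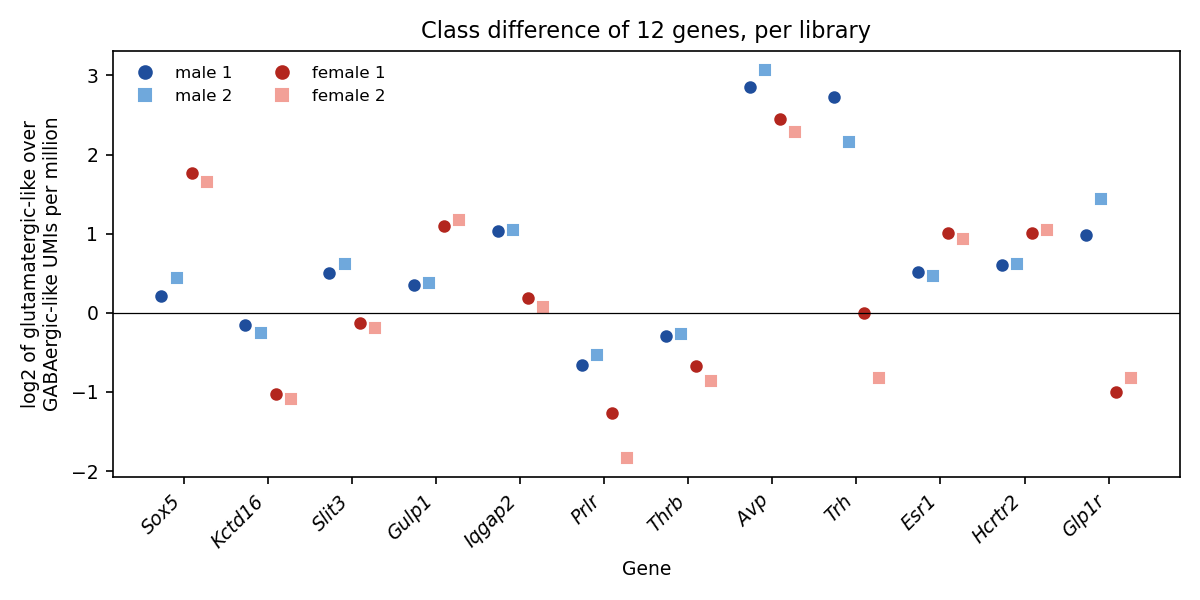
Log2 of CPM in glutamatergic-like over GABAergic-like neurons for 12 genes whose sex effect differed between these classes, 1 point per library (2 males, 2 females). Sox5 lies lower in the males (171 over 147 CPM in male 1) than in the females (297 over 87.2 CPM in female 1), and Prlr lies higher in the males.

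To find neuron types that differed in frequency, the neurons were divided into 42 clusters after integration across libraries. Of these, 14 differed in their share of neurons, 8 higher in males and 6 higher in females. Neuron cluster 40, a GABAergic-like cluster led by the estrogen receptor gene Esr2 with St18 and Moxd1, made up 0.97% of male and 0.09% of female neurons (log2 fold 3.43 ± 0.31 SE, adjusted p = 0.000102 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), from 56 and 47 nuclei in the males and 5 and 6 in the females. Neuron cluster 36, GABAergic-like and led by Adamts6 and Zbtb7c, made up 1.47% against 0.2% (2.86 ± 0.28, adjusted p = 0.000102). Without integration 92.8% of the nuclei of cluster 36 joined a cluster in which they were 20.1% of nuclei, with a log2 fold of 1.78 there, so it was not separate in that setting. Neuron cluster 42, led by Pappa2 and Hmcn1, held 15 and 18 male nuclei and 1 in each female (ratio of shares 19.4, counting interval 4.96 to 167, adjusted p = 0.000351). Clusters 24, led by Dnah5, Vipr2 and the dopamine receptor gene Drd3 (3.13% against 1.04%, log2 fold 1.59 ± 0.23, adjusted p = 0.00123), 17, led by Nxph2 and Adarb2 (3.96% against 1.6%, adjusted p = 0.00148), and 26, glutamatergic-like and led by Rorb with Slc17a7 (2.53% against 1.16%, adjusted p = 0.00515), were also higher in males, as were 25 (log2 fold 0.83) and 6 (0.76).

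The clusters higher in females were 2, with Isl1 among its leading genes (4.52% of male and 8.37% of female neurons, log2 fold -0.89 ± 0.21 SE, adjusted p = 0.0115, edgeR), 21, led by Il1rapl2 and Tac2 (1.44% against 2.82%, -0.97 ± 0.20, adjusted p = 0.00795), 18 (1.53% against 3.49%, -1.19 ± 0.27, adjusted p = 0.0115), and 16 (-0.80), 15 (-0.75) and 31 (1.2% against 1.97%). All 14 had both males on 1 side of both females, while 21 of 42 had an unadjusted p under 0.05. Such separation adds no support to a call, since many clusters that were not called had it too. Cluster 12, for example, lay at 3.42% and 3.54% in the males and 3.18% and 3.25% in the females (adjusted p = 0.667, edgeR). Male and female neurons differed in depth, and nuclei of cluster 18 held a median of 0.24 times the UMIs of their library's neurons. The count of called clusters was 3 without male 1, 4 without male 2, 28 without female 1 and 27 without female 2, and clusters 40, 36 and 42 were called in all 4 fits. When neurons were thinned to the shallowest library's depth before clustering, an alternative added after seeing the data, 13 clusters were called, and 94.7% of the nuclei of cluster 40 joined a larger cluster in which they were 11% of nuclei, with a log2 fold of 0.51 there.

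**Figure D5:**
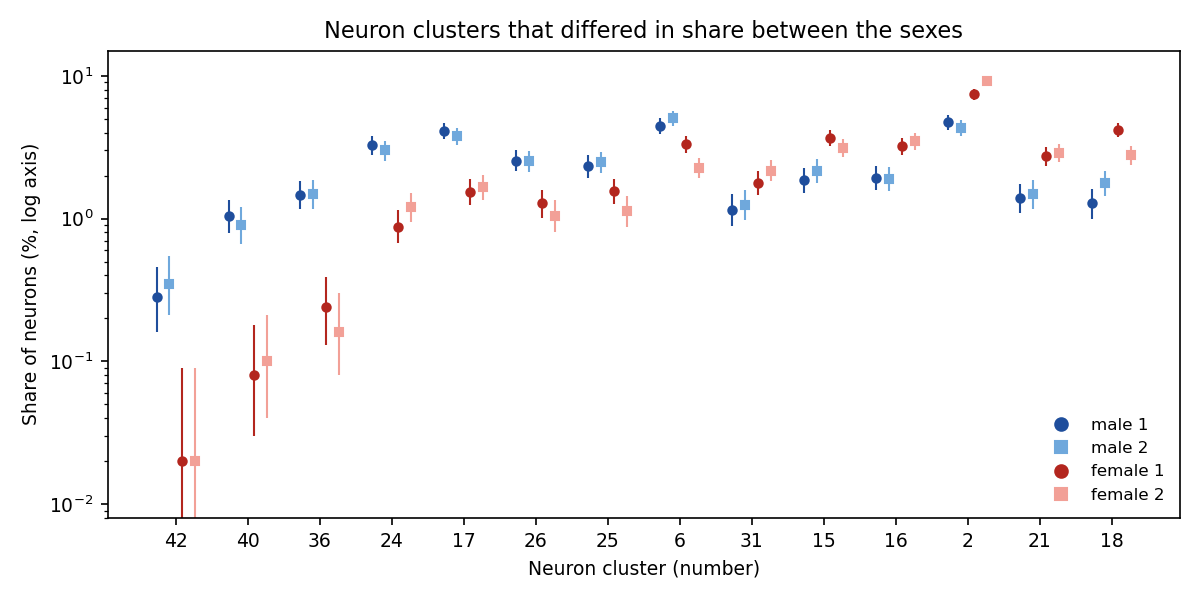
Share of neurons (%, log scale) in the 14 neuron clusters that differed between the sexes, 1 point per library with exact 95% binomial intervals (counting error only; intervals of the females in cluster 42 run below the axis). Cluster 40 lies at 1.04% and 0.9% in the males and 0.08% and 0.1% in the females.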

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

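The tests weighed here on doublets, tissue pieces, deeper sequencing and cluster shares were chosen only after the data had been seen, and for the depth gap in the class interaction the thinned fit was planned but its bounds were set after its result. The sex effect differed between GABAergic-like and glutamatergic-like neurons, by a test of the difference itself, for 290 genes (edgeR quasi-likelihood interaction, Benjamini-Hochberg adjustment). Log2 folds in glutamatergic-like minus those in GABAergic-like neurons were -1.39 for Sox5, 0.85 for Kctd16, 0.72 for Slit3, -0.78 for Gulp1, 0.90 for Iqgap2, 0.91 for Prlr and 0.48 for Thrb, and each of these 7 was called without any 1 library. With Leiden cluster 14 alone as the glutamatergic-like neurons, Slit3, Gulp1 and Thrb were not called (0.20, -0.11 and 0.04), and the other 4 were.

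The vasopressin gene Avp had a difference of 0.61 (adjusted p = 0.00793, edgeR), lost without male 2 or female 2, with a largest adjusted p of 0.104. For the thyrotropin-releasing hormone gene Trh it was 3.04 (adjusted p = 0.0151), lost without male 1 or female 2 (0.337). For Esr1 it was -0.48 (adjusted p = 0.0205), with 39.3 and 35.2 CPM in male against 46.7 and 44.1 CPM in female glutamatergic-like neurons, lost without male 1, male 2 or female 1 (0.157). The orexin receptor gene Hcrtr2 had -0.42 (adjusted p = 0.0292), lost without male 1, male 2 or female 2 (0.225), and the incretin receptor gene Glp1r 2.09 (adjusted p = 0.0311), lost without male 2, female 1 or female 2 (0.149).

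For the class interaction, 3 explanations were weighed. The depth gap between the sexes stays open. A share of 0.803 of the called genes was called again after thinning all libraries to the lowest, but thinning summed counts leaves the expected ratios as they are, so this decides nothing. A different makeup of the glutamatergic-like neurons in each library stays open. With Leiden cluster 14 alone, the median ratio of the difference to the full value was 0.68, so part of the difference was lost and part was not, and this explanation and a sex effect within cells cannot be told apart. The GABAergic-like sum kept all its clusters in that fit, so the makeup of that class was not tested. Of its Leiden clusters, cluster 3 drew 97.8% of its nuclei from female 1 and cluster 13 drew 82.2% from female 2. The part of the difference that was kept may therefore also come from the makeup of the GABAergic-like neurons. Sex of the animals stays open as an untested biological explanation. The software that changed with it, and the chemistry if that changed too, may contribute as well.

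For the 8 neuron clusters more frequent in males, among them the Esr2-led cluster 40, doublets stay open. The median UMIs of a cluster's nuclei over those of their library's neurons had a median of 1.05 over the 8 clusters, with 0.93 in cluster 40 and a range from 0.72 in cluster 25 to 1.49 in cluster 42. Deeper male sequencing, acting on how kept neurons clustered, is argued against as the whole cause for clusters 17, 24, 26, 36 and 42. These 5 of the 8 kept a log2 fold above 1 in the cluster that matched them best after thinning. Thinning followed the filters, doublet removal and class naming, all done at full depth. Depth acting through the choice of nuclei therefore stays open for all 8. Depth acting on the clustering stays open for the other 3 as a set, of which 1 kept at least 0.9 of its fold. Cluster 25 went from 0.83 to 0.80 and stayed called, cluster 6 from 0.76 to 0.62 and lost its call (adjusted p = 0.0682), and cluster 40 was not separated there. Clusters 25 and 6 lay below 1 before thinning. Dissection of different tissue pieces stays open. The shares of 1 cluster (neuron cluster 27, 0.8% in female 1 and 3.38% in female 2) differed between the females by 2.06 on the log2 scale, above the smallest and below the largest of the 8 sex differences. Sex of the animals is untested beside it. The 8 differences may come from any of these, within the limit on depth given above for clusters 17, 24, 26, 36 and 42.

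A signal also lay outside the genes compared, since UMIs on genes missing from the common list made up 0.46% of male 1, 0.46% of male 2, 2.26% of female 1 and 0.40% of female 2, with no control sample to set them against.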

How the results depend on the processing

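Alternatives added after seeing the data were: no upper limit on genes, males summed as 1, no genes overlapped by gene models of female 1 alone, no clusters mostly from 1 library, cluster 14 alone, neurons thinned before clustering, no mixed clusters and mixed clusters (all, or those with neuron markers) counted with the neurons. Over 200 alternatives for 13 results, 96 stayed on the same side of the test and within 1.5 times the count, 102 moved a count by more, and 2 turned a direction. Called genes are given for neurons, GABAergic-like, glutamatergic-like and cholinergic-like neurons, then astrocyte-, oligodendrocyte-, OPC- and microglia-like nuclei, and the cause was not tested unless given. DESeq2 called 1258, 1132, 593, 89, 79, 95, 79 and 19, and 93 for the class interaction. Leaving out 1 library gave 3 to 12450, 3 to 11514, 310 to 6537, 6 to 1422, 29 to 4625, 30 to 4538, 40 to 2091 and 25 to 510, with the high ends always without a female, where the remaining spread came from the near-identical males and the lone female is assumed to vary like them. It gave 182 to 543 for the interaction, 4 to 14 for gene lists, 0 to 7 for class shares and 3 to 28 for neuron clusters.

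Without a low-count filter the counts were 3 in neurons and GABAergic-like neurons, 616 cholinergic-like, 396 astrocyte-like, 373 oligodendrocyte-like, 301 OPC-like and 144 microglia-like. Thinning gave 3, 3, 9 astrocyte-like, 5 oligodendrocyte-like and 18 OPC-like. Males summed as 1 gave 3, 3, 331 glutamatergic-like, 39, 22, 57 and 42 in the glial classes. Without the overlapped genes the counts were 3, 3, 5 cholinergic-like and 6 oligodendrocyte-like, and without clusters mostly from 1 library 2 and 2. Doublets kept gave 6 cholinergic-like, 6 astrocyte-like, 6 oligodendrocyte-like and 17 OPC-like, at least 1000 genes 6, 8 and 20 in the last 3, no upper limit on genes 5 cholinergic-like, and median-ratio factors 19 OPC-like. Cluster 14 alone gave 159 interaction genes, with fewer nuclei. An estimated correlation left 0 lists, and either way of counting mixed clusters with the neurons 3. For class shares, at least 1000 genes, a mitochondrial share under 1%, resolution 2 and no upper limit gave 1 each, and resolution 0.5 gave 8 neuron clusters. The GABAergic-like share difference ranged from -2.78 (without female 1) to 1.53 points (without female 2, turning its direction) and was 0.43 points at resolution 2.

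The labels tie the replicate numbers to nothing shared between the sexes, and 2 pairs cannot show whether they pair the samples (correlation of deviations 0.118 in neurons). With the number as a block, 5, 52, 804, 6, 307, 312 and 75 genes were called in the classes from neurons to OPC-like nuclei, 1 class share and 7 neuron clusters. Depth limits the females, whose neurons held median UMIs of 5083 and 4886 against 11654 and 11352 in the males.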

Other observations

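Of the tests in this part, that on gene models was chosen only after the result had been seen, and that on depth was set out before. Some hormone and peptide genes differed between neuron classes, and those named in this paragraph had the same sign in all 4 libraries. Relative to GABAergic-like neurons, glutamatergic-like neurons had more Esr1, at 40.7 ± 4.73 against 24.3 ± 2.4 CPM (SD, n = 4; log2 fold 0.70 ± 0.08 SE, adjusted p = 1.12e-06 by edgeR's quasi-likelihood test with library as a term), and more of the peptide genes Adcyap1 (3.68), Avp (2.73), Oxt (2.03) and Cck (1.72). They had less Cyp19a1 (-1.51), Penk (-1.11), Crh (-1.73) and Tacr3 (-2.46). Over all genes 3225 of 15340 differed, 1662 higher and 1563 lower. Of 17 steroid receptor and enzyme genes 2 were higher and 5 lower (7 adjusted over the list alone), of 18 neuropeptides 4 higher and 9 lower (14), and of 34 peptide and hormone receptors 7 higher and 9 lower (17).

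Some receptor genes were higher in cholinergic-like neurons and more were lower. The substance P receptor gene Tacr1 lay at 279 ± 60.6 CPM against 39.8 ± 12.1 CPM in GABAergic-like neurons (SD, n = 4; log2 fold 2.79 ± 0.10 SE, adjusted p = 2.7e-15, edgeR), the delta opioid receptor gene Oprd1 at 81.2 ± 8.94 against 16.2 ± 1.56 CPM (2.31 ± 0.10, adjusted p = 1.56e-13) and Esr2 at 31.1 ± 3.96 against 5.6 ± 2.88 CPM (2.40 ± 0.23, adjusted p = 4.1e-08), each in 4 of 4 libraries. Tacr3 (1.40) and Esr1 (0.82) were also higher, and Prlr (-2.68) was lower. In all 4922 genes differed, 2331 higher and 2591 lower, with 3 higher and 6 lower among steroid genes (9 adjusted over the list alone), 0 and 8 among neuropeptides (10) and 6 and 13 among peptide and hormone receptors (19).

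Of 9457 genes outside chromosomes X and Y tested in at least 6 classes, 67 had a male over female log2 fold of at least 2 in size with the same sign in at least 6 classes, 7 higher and 60 lower in males and 16 of them protein coding. The classes come from the same 4 libraries. The neurons, counted as a class, also contain the GABAergic-like, glutamatergic-like and cholinergic-like neurons, so agreement between classes is not independent. Neuron values were 7.19 for Evi2b, 5.50 for Mapkapk5, 4.70 for Arfip1, -6.04 for Gm11867, -3.89 for mt-Nd2, -2.69 for Nrg3os and -2.53 for Ptgds. A depth gap stays open, since thinning left 1.01 of the median size (2.77 against 2.74) but leaves the expected ratios of summed counts as they are, so this decides nothing. Reads assigned by different gene models stay open. Of these genes 85.1% overlap another gene, against 62.2% of all such genes (Fisher's exact test, two-sided, p = 6.4e-05). Most of the 67 were not protein coding, however, and the 2 sets were not matched by gene type. The test therefore cannot tell gene models from gene type. Sex stays open as an untested explanation, as do the software versions that changed with it.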
